A study of Mus musculus with 9 samples.

How the data were processed

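RNA sequencing measured gene expression in macrophages that had been sorted by flow cytometry, as F4/80+ CD11b+ cells, from the non-parenchymal cells of livers of male C57BL/6 mice 24 hours after 1 intraperitoneal injection of carbon tetrachloride (CCl4), a hepatotoxin, at 0.6 mg/kg as labelled (the unit could not be checked, and doses of this agent are often given by volume). Per the labels, 5 mice were MAGL Mye-/- and 4 were MAGL fl/fl controls. MAGL is monoacylglycerol lipase, the product of Mgll. All 4 fl/fl mice were 11 weeks old, whereas 3 of the 5 Mye-/- mice were 10 weeks old and 2 were 11 weeks old, so age was partly tied to genotype. The groups share no replicate numbers and the labels give no batch. The libraries carry separate sample names, and p-values assume that each came from a separate mouse.

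The deposited table is a signal table of normalized read values. The authors divided read counts by 1 size factor per sample with DESeq, per the file headers and the submitters' processing notes, without a log and without correction for gene length. Those notes name STAR 2.4.0, SAMtools, Picard, FastQC and the mm10 build, and the file headers name mm10 coordinates and FAST DB gene models. The counting tool, the strand setting and the treatment of duplicate reads were not given in the sources used here, so overlapping, antisense and near-identical genes cannot be separated. Every value was a whole multiple of the smallest value of its column, within a tolerance of 0.01 reads (100% of nonzero values in each library), which gave back whole reads. Library totals ran from 33383559 to 46489349 reads. Between 66.1% and 68.3% of nonzero counts under 1000 reads were even, as when both mates of a pair are counted, and the numbers of reads per low feature piled up at 24 to 70 reads depending on the library, so reads of low genes are not separate molecules. No molecular identifiers were recorded, and reads therefore understate the error of low genes.

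The table holds 59445 features. A symbol from the table was used where there was one. Of the 35957 features without a symbol, 5853 took the name of a GENCODE M21 gene (GRCm38, the assembly of mm10) whose interval matched with a Jaccard overlap of at least 0.8, and 30104 kept the table's own identifier. GENCODE M21 also gave strand, exon and intron positions, transcript length and GC content.

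The main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(normalized value + 1), comparing 5 Mye-/- with 4 fl/fl libraries, on the 15288 features with a value of at least 10 in at least 4 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are Mye-/- minus fl/fl on that scale. For genes with values at 0 in some libraries they depend on the pseudocount and lie above or below those of the count models, for example 5.08 for Clec4f against 3.27 with DESeq2. Of 35 gene lists fixed before the data were examined, 33 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists. A list score is the mean over members of the log2 value centred on each gene's mean. Exact permutation tests of scores and of Mgll used all 126 regroupings of the 9 libraries, two-sided. Their smallest possible p is 0.00794, so 1 list score alone cannot pass after adjustment over 33 lists. In the same design on simulated counts, limma recovered 26.9% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 98.5% of those changed 4-fold, among genes with a mean of at least 500, with 10 calls among 15048 unchanged genes. The simulation changed 200 genes besides a list, which loosens the adjusted threshold, so recovery may be lower where few genes change. In that simulation camera called 2 of the 32 lists other than the one changed on purpose, and 0 of the 17 lists without a changed member. Simulated genes vary independently and real ones do not: on the measured libraries camera at the preset correlation called at least 1 list in 97 of 99 other splits of the samples, with a median of 6.

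Most genes named in the Results were chosen by a rule fixed before the data were examined. They are Mgll, the up to 15 genes per direction with the largest change among those past the threshold with a symbol and a mean of at least 50 in the higher group (or, with fewer than 5, the 5 with the smallest p, given as not passing), up to 4 members with the smallest p of each called list and of 9 lists fixed in advance, and Lyz2, Adgre1 and Itgam as identity genes. The feature GSMG0067294 passed the threshold outside that rule and was named after its values were seen. Atf3 and the further genes under Other observations were also named outside it.

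Alternatives fixed before the data were examined were pseudocounts of 0.5 and 8, other filters, TMM scaling, quantile normalization, robust and untrended limma, array weights, age as a covariate, 11-week-old mice only, leaving out each library, camera with an estimated correlation or on ranks, and fry. On the recovered whole reads, edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma-voom were run. Adjusted p-values of genes and counts of list members that passed are from limma unless another tool is named. A pseudocount of 50, a mean of at least 500, the number of detected features as a covariate, and a fit without fl/fl S1 and S3, the libraries farthest out on the leading principal components, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.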

Results

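Transcript levels were measured in F4/80+ CD11b+ liver macrophages of 5 MAGL Mye-/- mice (S8 to S12) and 4 MAGL fl/fl mice (S1, S3, S4 and S5), 24 hours after CCl4. The comparison asks how liver macrophages of mice labelled as lacking myeloid MAGL (monoacylglycerol lipase, the enzyme that splits the endocannabinoid 2-arachidonoylglycerol into arachidonic acid and glycerol) differ from control macrophages during acute liver injury. Libraries held 33383559 reads (fl/fl S1) to 46489349 reads (Mye-/- S9). Features with at least 1 read numbered 15547 in fl/fl S1, 14696 in S3, 14240 in S4 and 16385 in S5, and 16231, 16802, 15614, 15873 and 16513 in Mye-/- S8 to S12. Features of the mitochondrial chromosome took 3.49% to 9.45% of reads, with the highest share in fl/fl S3. The feature of the ribosomal RNA precursor Rn45s took 0.20% to 1.05% of reads in fl/fl, highest in S3, and 0.12% to 0.28% in Mye-/-. Spearman correlations across genes between libraries ran from 0.922 to 0.964. The sorted cells' identity genes were abundant. Itgam, which encodes CD11b, was at 48739 ± 7072 normalized reads in fl/fl (SD, n = 4) and 49711 ± 4679 in Mye-/- (SD, n = 5). Adgre1, which encodes F4/80, was at 5433 ± 658 and 6443 ± 1054. Neither passed the test (limma adjusted p = 0.955 and 0.581).

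Mgll (chromosome 6, 88724412 to 88828360, mm10, plus strand) was close to the detection limit in both genotypes. Its normalized values were 18.6, 0, 106.5 and 22.8 in fl/fl S1, S3, S4 and S5, from 16, 0, 122 and 26 reads. In Mye-/- S8 to S12 they were 30.4, 46.6, 5.93, 42.7 and 0. The means were 37.0 ± 47.4 (SD, n = 4) and 25.1 ± 21.2 (SD, n = 5), and the difference was within the spread (two-sided exact permutation p = 0.730). These levels lie at the size of the low-count pile-ups, and the part of the gene removed by the deletion was not given in the sources used here, so Mgll did not check the labels. A loss of Mgll was not detectable at this depth.

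In Mye-/- macrophages 3 of 15288 features rose and 0 fell (limma, adjusted p under 0.05). Mat2a, which encodes the catalytic subunit of the methionine adenosyltransferase that makes S-adenosylmethionine, rose from 1437 ± 185 (SD, n = 4) to 3233 ± 411 (SD, n = 5), a log2 fold change of 1.17 ± 0.16 (SE, adjusted p = 0.0123). Id1, an inhibitor of basic helix-loop-helix factors, rose from 4795 ± 975 to 9159 ± 1235 (log2 fold change 0.94 ± 0.15 SE, adjusted p = 0.0264). The third was GSMG0067294, a feature without a symbol at 75694819 to 75696041 of chromosome 2. It lies inside an intron of Nfe2l2, touches no annotated exon, and rose from 720.2 ± 84.5 to 1690.3 ± 158 (log2 fold change 1.23 ± 0.19 SE, adjusted p = 0.0264). In each of the 3, all 5 Mye-/- values were above all 4 fl/fl values. The next genes missed the threshold. Nr4a2, an orphan nuclear receptor of the immediate-early class, was at 6962 ± 1981 in fl/fl and 15379 ± 3597 in Mye-/- (adjusted p = 0.0506). Klf4, a transcription factor of monocytes and macrophages, was at 13589.7 ± 2216 and 22837 ± 2219.9 (adjusted p = 0.0608), and Leng8 at 2979 ± 738 and 6145 ± 1114 (adjusted p = 0.0583). Among lower genes, Lcn2, the siderophore-binding acute-phase protein lipocalin 2, was at 11243 ± 1974 in fl/fl and 6357 ± 900.2 in Mye-/- (adjusted p = 0.0608). Snrpd3, a core protein of spliceosomal snRNPs, was at 4401 ± 441 and 2655 ± 518 (adjusted p = 0.162). Over 27 alternatives the call was lost in 6 for Mat2a, 10 for Id1 and 9 for GSMG0067294, while Nr4a2 passed in 12, Leng8 in 11, Klf4 in 11 and Lcn2 in 7. At an unadjusted p under 0.05 there were 1608 features. On the whole reads edgeR called 2 features and DESeq2 called 146, of which 91 were higher and 55 lower. The limma count was 0 with age as a covariate, among 11-week-old mice, with the number of detected features as a covariate, without Mye-/- S8 and without Mye-/- S10. It was 1 without Mye-/- S11, 5 without fl/fl S3 or Mye-/- S9, 7 without fl/fl S1 and 20 without fl/fl S5.

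**Figure D1:**
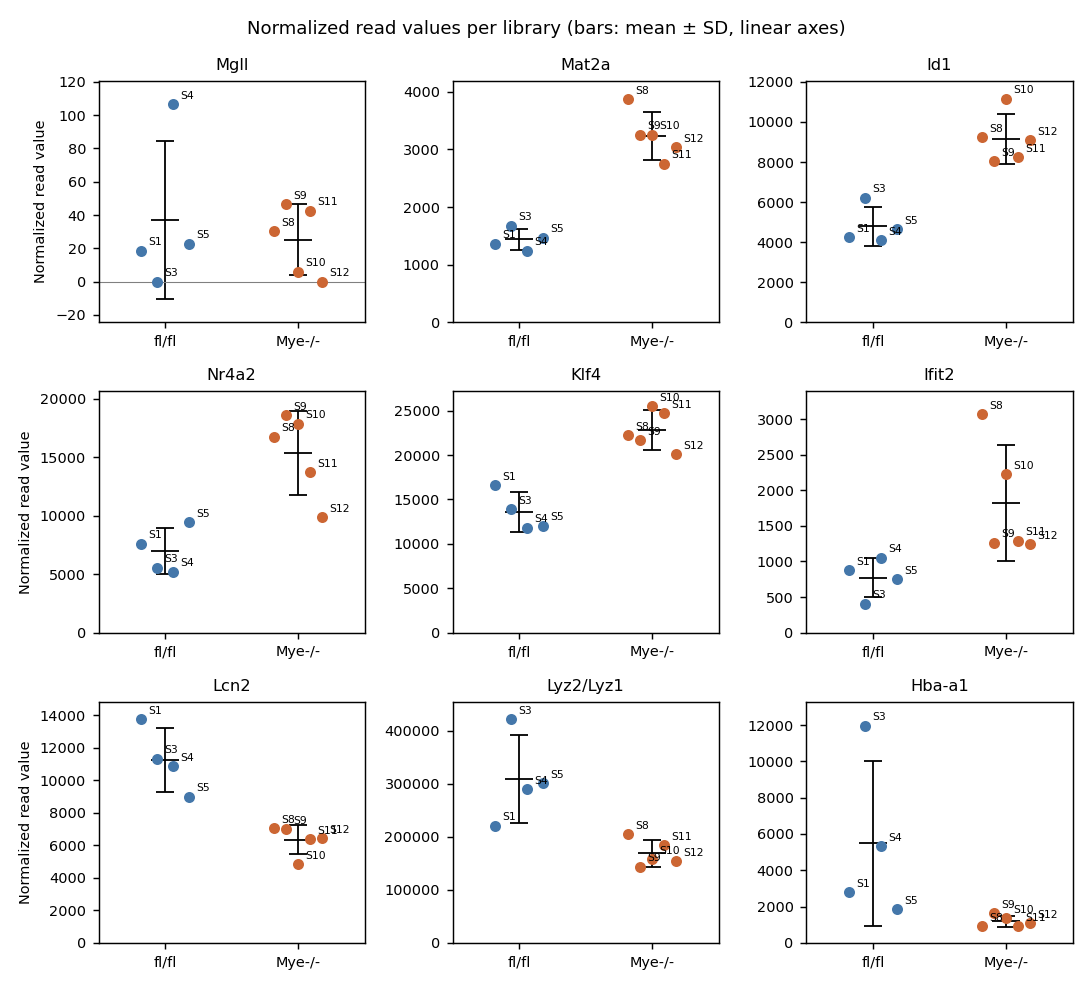
Normalized read values of 9 named genes in each library (vertical linear axes, in normalized reads), with fl/fl libraries in blue, Mye-/- libraries in orange, and black bars for the mean ± SD of n = 4 and n = 5. Mat2a, Id1, Nr4a2, Klf4 and Ifit2 are higher in every Mye-/- library than in any fl/fl library. Lcn2, the Lyz2/Lyz1 feature and Hba-a1 are lower in every Mye-/- library, and Mgll overlaps between the genotypes near 0.

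Type I interferon response genes rose as a list in Mye-/- macrophages. Of 52 measured genes of this list, 48 were higher and 4 lower, with a median log2 fold change of 0.62 (camera adjusted p = 3.2e-16; adjusted p = 0.276 with an estimated correlation). At an unadjusted p under 0.05, 28 were higher and 0 lower. None passed when adjusted over all genes, and 22 rose when adjusted over the list alone. Among the latter, Ifit2, an interferon-induced protein that restricts viral translation, was at 772 ± 272 normalized reads in fl/fl (SD, n = 4) and 1817 ± 815 in Mye-/- (SD, n = 5), a log2 fold change of 1.21 ± 0.30 (SE). Rsad2, which encodes the antiviral protein viperin, went from 158 ± 108 to 516 ± 134, Mx1, an antiviral GTPase, from 772 ± 330.3 to 1787 ± 773, and Ifih1, the RNA sensor MDA5, from 2150.2 ± 225 to 3510.3 ± 736. These 4 genes had limma adjusted p = 0.218 over all genes, while DESeq2 called Ifih1 and Ifit2 (adjusted p = 0.0260 and 0.0409). The list score was -0.36 ± 0.35 (SD) in fl/fl and 0.29 ± 0.31 in Mye-/- (two-sided exact permutation p = 0.0397, adjusted p = 0.164 over the 33 lists), and fl/fl S5, at 0.13, lay above Mye-/- S9 and S12. Without fl/fl S1 and S3, a choice made after the values were seen, the median was 0.30 and 0 members passed when adjusted over the list alone. That number was also 0 without Mye-/- S8, among 11-week-old mice, without an intensity trend and with detected features as a covariate, 6 without fl/fl S3, 9 without fl/fl S1 or with array weights, and 14 without Mye-/- S10.

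Immediate-early and stress genes of the kind induced by tissue dissociation also rose. Of 24 measured members 22 were higher, with a median log2 fold change of 0.29 (camera adjusted p = 1.7e-06; adjusted p = 0.276 with an estimated correlation). Besides Nr4a2 and Klf4, Fosb, a subunit of the AP-1 transcription factor, was at 20131 ± 4403 in fl/fl and 32189.9 ± 5409 in Mye-/-, and Klf6 at 4709 ± 1106 and 6956 ± 1516. Adjusted over the list alone 5 members rose, namely these 4 and Atf3, a stress-response transcription factor, and 0 passed over all genes with limma. DESeq2 called Nr4a2, Klf4, Fosb and Atf3 over all genes.

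Markers of Kupffer cells, the resident liver macrophages, rose as a list (19 measured, 14 higher, median 0.94, camera adjusted p = 0.00145; adjusted p = 0.244 with an estimated correlation). Most were low, and among the 6 members with a mean of at least 500 the median was 0.62. Id1 passed over all genes, and 4 members rose when adjusted over the list alone, Id3, the Kupffer identity factor related to Id1, among them, at 14736 ± 4568 in fl/fl and 24792 ± 4398 in Mye-/-. Hpgd, which inactivates prostaglandins, was at 349.7 ± 237 and 787 ± 402. Clec4f, a lectin restricted to Kupffer cells, was at 0 in 3 fl/fl libraries and 73.8 in fl/fl S5, and at 33.3 to 603 in Mye-/-, with the highest value in S10. The list's median was 0.62 without fl/fl S4, 0.44 with a pseudocount of 50 and 0.37 without fl/fl S1 and S3 (adjusted p = 0.0334).

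Phagocytosis and efferocytosis genes rose with 21 of 26 members higher (median 0.26, camera adjusted p = 0.0179; adjusted p = 0.367 with an estimated correlation), and 0 members passed either adjustment. Itgav, an integrin subunit that binds apoptotic-cell bridging proteins, was at 2277 ± 537 and 3248 ± 366, Thbs1, which encodes thrombospondin 1, at 98045 ± 39193 and 140421 ± 13005, Mertk, a receptor for apoptotic cells, at 235 ± 170.4 and 481 ± 107, and its ligand Gas6 at 5.8 ± 11.6 and 108 ± 140.1, with 358 in Mye-/- S10. The call was lost without fl/fl S3 (median 0.06, adjusted p = 0.367), without Mye-/- S10, S11 or S12 (adjusted p = 0.05003 to 0.0530) and without fl/fl S1 and S3 together (median 0.10, adjusted p = 0.658). It was also lost among genes with a mean of at least 500 (median 0.12, adjusted p = 0.143), with detected features as a covariate (median 0.08, adjusted p = 0.0861) and without an intensity trend (adjusted p = 0.0662).

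Hepatocyte markers also rose as a list (19 measured, 17 higher, median 1.19, camera adjusted p = 0.00214; adjusted p = 0.367 with an estimated correlation). Among their 3 members with a mean of at least 500 the median was 0.02. Mye-/- S10 held the most hepatocyte RNA, with a list score of 2.74 against -0.07 to 0.33 in the other Mye-/- libraries. Hpx, which encodes hemopexin, was at 119.6 ± 63.5 in fl/fl and 413 ± 323 in Mye-/-, Rbp4 at 20.4 ± 33.4 and 116 ± 74.8, Fgg at 55.0 ± 79.5 and 214 ± 307, and Ttr at 41.5 ± 82.9 and 229 ± 435. No hepatocyte member passed either adjustment. The call was lost without Mye-/- S10 (median 0.67, adjusted p = 0.153), and with age as a covariate or among 11-week-old mice (median 0.62, adjusted p = 0.161 and 0.147). The median was 0.77 with a pseudocount of 50.

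**Figure D2:**
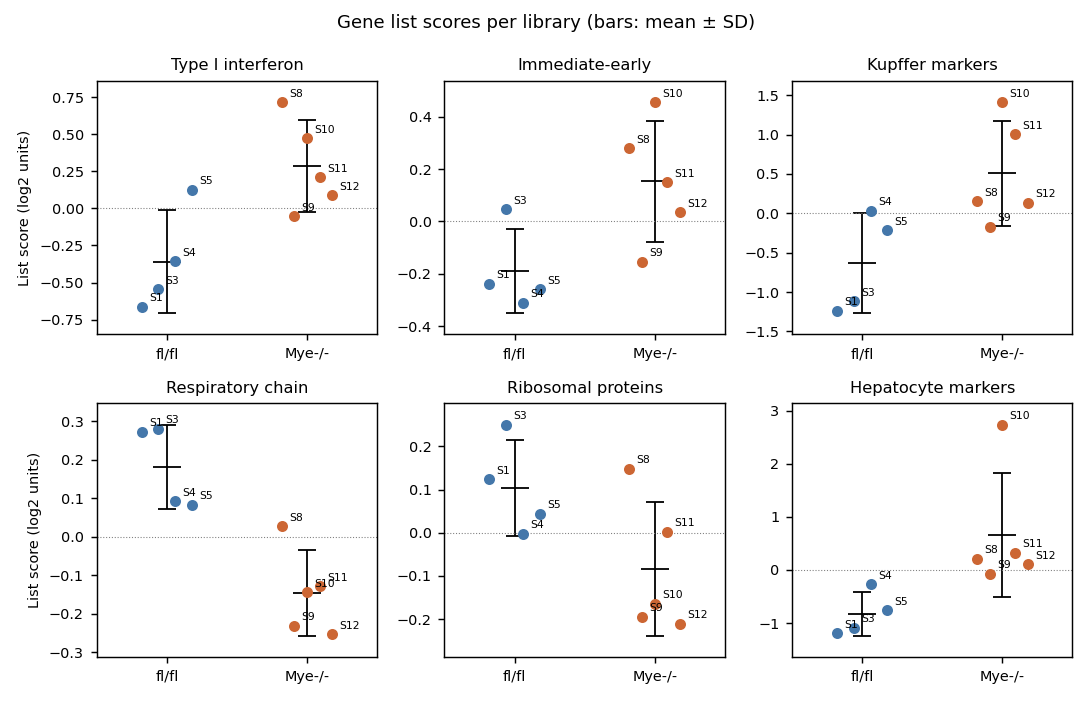
Scores of 6 gene lists in each library (vertical axes, mean centred log2 value over the list's members), with fl/fl libraries in blue, Mye-/- libraries in orange, and black bars for the mean ± SD of n = 4 and n = 5. Respiratory chain scores of all 5 Mye-/- libraries lie below those of the 4 fl/fl libraries, the interferon scores overlap through fl/fl S5, and Mye-/- S10 stands apart in hepatocyte markers.

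Genes for energy metabolism and protein production fell as lists in Mye-/- macrophages, by small amounts. All 50 nuclear genes of the respiratory chain were lower, with a median log2 fold change of -0.33 (camera adjusted p = 1.7e-21; adjusted p = 0.196 with an estimated correlation). Adjusted over the list alone 12 fell, and 0 passed over all genes with limma. DESeq2 called Ndufb7 over all genes (adjusted p = 0.0458). Ndufb7 and Ndufs6, subunits of complex I, were at 4237 ± 457 and 4326 ± 419.7 in fl/fl (SD, n = 4) and at 2902 ± 384 and 2957 ± 456 in Mye-/- (SD, n = 5). Ndufv2 was at 6809 ± 1083 and 4864 ± 934, and Cox8a, a subunit of complex IV, at 7275 ± 1807 and 5060.3 ± 482. The list score was 0.18 ± 0.11 (SD) in fl/fl and -0.15 ± 0.11 in Mye-/-, and lower in all 5 Mye-/- libraries than in any fl/fl library (two-sided exact permutation p = 0.0159, adjusted p = 0.131 over the 33 lists). The hepatocyte, reparative, and NRF2 and iron scores separated the genotypes as fully, all higher in Mye-/-, with the same p. For respiratory chain genes the number adjusted over the list alone was 0 without any 1 of fl/fl S3, fl/fl S5, Mye-/- S9, S11 or S12, 5 without Mye-/- S10, 6 without fl/fl S1 or S4, and 16 without Mye-/- S8. It was 17 with DESeq2, 6 with a pseudocount of 50, 2 with a pseudocount of 0.5 or 8, TMM scaling, quantile normalization or array weights, and 0 without a filter, with robust or untrended limma, with age or detected features as a covariate, among 11-week-old mice, with edgeR or limma-voom, and without fl/fl S1 and S3. Features without a symbol inside introns, 941 in number, had a median log2 fold change of 0.53, against a median of 0.38 (0.25 to 0.51) in random lists of named genes at the same expression level. They took 0.257% ± 0.0137 of reads in fl/fl (SD, n = 4) and 0.299% ± 0.0345 in Mye-/- (SD, n = 5; two-sided exact permutation p = 0.0635).

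Ribosomal protein genes fell with 49 of 54 lower (median -0.19, camera adjusted p = 3.5e-10, and 0.353 with an estimated correlation), and no member passed either adjustment with limma. DESeq2 called Rpl21 and Rplp2 over all genes (adjusted p = 0.0324 and 0.0424). Rpl21 was at 7166 ± 1723 and 4672 ± 429, Rplp2 at 14966 ± 2127 and 10943 ± 1011, Rpl8 at 53006 ± 8014 and 40261 ± 3569.6, and Rplp1 at 35171 ± 4607 and 27196 ± 2399. The median was -0.11 without fl/fl S1 and S3. Targets of the unfolded protein response fell with 18 of 24 lower (median -0.19, camera adjusted p = 0.000248, and 0.276 with an estimated correlation). The list score gave a two-sided exact permutation p = 0.286. Adjusted over the list alone 5 fell and 1, Atf3, rose. Over all genes DESeq2 called 4 members as lower, Pdia4, Dnajc3 and Sdf2l1 among them, and 1, Atf3, as higher. Pdia4, a disulfide isomerase of the endoplasmic reticulum, was at 10387 ± 1016 in fl/fl and 6719.6 ± 1555 in Mye-/-, Dnajc3 at 3397 ± 532 and 2220.0 ± 299, Creld2 at 3545 ± 91.4 and 2320.1 ± 510.1, and Sdf2l1 at 9599.9 ± 2392 and 6340.0 ± 712. The call was lost with age as a covariate and among 11-week-old mice (adjusted p = 0.113 and 0.111).

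Glycolysis and hypoxia genes, tested together as a list, fell with 19 of 24 lower (median -0.17, camera adjusted p = 0.00642, and 0.629 with an estimated correlation), and 0 members passed either adjustment. The list score gave a two-sided exact permutation p = 0.556. Hypoxia genes such as Vegfa are part of this list. Among enzymes of glycolysis, Eno1 was at 36435 ± 6467 in fl/fl and 27108 ± 2584 in Mye-/-, Hk1 at 5593 ± 967 and 4313 ± 411, and Pgk1 at 18226 ± 5935 and 13162 ± 1294, whereas Pfkfb3, which makes an activator of glycolysis, was at 1918 ± 1032 and 2837 ± 409. The glycolysis and hypoxia call was lost without fl/fl S5 (median -0.04, adjusted p = 0.756), with age as a covariate or among 11-week-old mice (median -0.08, adjusted p = 0.364 and 0.389) and with quantile normalization (adjusted p = 0.0529). Its median was -0.33 without fl/fl S3, -0.35 with detected features as a covariate and -0.34 without fl/fl S1 and S3. Fatty acid oxidation genes fell with 24 of 34 lower (median -0.19, camera adjusted p = 0.00738; adjusted p = 0.244 with an estimated correlation), again with 0 members past either adjustment. Etfa and Etfb, which pass electrons from fatty acid oxidation to the respiratory chain, were at 3570.5 ± 172 and 3487 ± 1031 in fl/fl and at 2505 ± 484 and 2368 ± 422 in Mye-/-. Decr1 was at 579.8 ± 295 and 269.9 ± 75.6. The feature that spans Cpt1b and Chkb was at 3284 ± 349.9 and 4307 ± 783, and reads of its genes cannot be separated. The call was lost without fl/fl S3 (adjusted p = 0.0620), among genes with a mean of at least 500 (median -0.10, adjusted p = 0.187), with detected features as a covariate (adjusted p = 0.112) and without fl/fl S1 and S3 (adjusted p = 0.178).

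Haemoglobin and a few neutrophil transcripts were lower in Mye-/- sorts. The platelet and erythroid list fell (12 measured, 6 higher and 6 lower, median -0.74, camera adjusted p = 0.00569, and 0.238 with an estimated correlation), and 4 haemoglobin features passed when adjusted over the list alone. The list score gave a two-sided exact permutation p = 0.357. Hba-a1 was at 5488 ± 4558 in fl/fl and 1179.8 ± 311 in Mye-/- (log2 fold change -1.89 ± 0.37 SE, adjusted p = 0.0832 over all genes), the feature of Hbb-bs and Hbb-b1 at 6395 ± 4866 and 1585 ± 843, Hba-a2 at 3450.1 ± 2440.1 and 667 ± 599, and the feature of Hbb-bt and Hbb-b2 at 1118 ± 1087 and 199 ± 157. Near-identical globin copies share reads. Hba-a1 was highest in fl/fl S3, at 11962. Without a filter on low values the list's median was 0.65. It was -0.28 without Mye-/- S9, -0.39 without Mye-/- S12 and -0.30 without fl/fl S1 and S3 (adjusted p = 0.0883), and the call was lost without an intensity trend (adjusted p = 0.0772) and with camera on ranks (adjusted p = 0.243). The median was -1.88 among features with a mean of at least 50, -1.14 with detected features as a covariate, -0.29 with edgeR, -0.30 with DESeq2 and -0.24 with a pseudocount of 50.

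Neutrophil markers fell with 12 of 17 lower (median -0.17, camera adjusted p = 0.0217, and 0.306 with an estimated correlation). Their list score barely differed between genotypes (0.04 ± 0.27 SD in fl/fl and -0.03 ± 0.49 in Mye-/-, two-sided exact permutation p = 0.833). Adjusted over the list alone 4 members passed. Besides Lcn2 these were S100a8 and S100a9, the subunits of calprotectin, and Wfdc21. S100a8 was at 30191 ± 8906 and 17455 ± 6352, S100a9 at 5906 ± 1444 and 2841 ± 2327, and Wfdc21 at 1568 ± 212 and 959 ± 279. S100a9 in Mye-/- S9 was at 6948. The list's call was lost without fl/fl S3 (adjusted p = 0.0618), Mye-/- S10 (median -0.07, 0.153) or Mye-/- S12 (0.0530), with age as a covariate (0.0514), on DESeq2's fold changes (0.0505), without a filter (median -0.07, 0.0764), without a trend (0.122), with camera on ranks (0.174) and without fl/fl S1 and S3 (median -0.06, 0.110). Its median was -0.11 without fl/fl S5, -0.26 without Mye-/- S8, -0.09 among 11-week-old mice, -0.08 with a pseudocount of 50 and -0.28 with detected features as a covariate.

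Cell cycle genes fell by a narrow margin (37 measured, 24 lower, median -0.25, camera adjusted p = 0.0494, and 0.276 with an estimated correlation), with 0 members past either adjustment. The list score gave a two-sided exact permutation p = 0.651. Of the 37, 7 had a mean of at least 500. Mcm3, a subunit of the replicative helicase, was at 726 ± 148 and 438 ± 126.2, Top2a at 142 ± 115 and 43.9 ± 44.0, Ube2c at 108 ± 61.3 and 22.7 ± 40.4, and Cdk1 at 15.3 ± 22.4 and 66.7 ± 69.6. The call was lost without any one of fl/fl S1, fl/fl S5, Mye-/- S8, S10, S11 or S12 (adjusted p = 0.05003 to 0.167), and the median was -0.38 without Mye-/- S9 or with DESeq2 and -0.62 with detected features as a covariate. It was also lost with a pseudocount of 0.5 (adjusted p = 0.0636), at a mean of at least 50 (0.0507) or 500 (0.124), with camera on ranks (0.0565) and without fl/fl S1 and S3 (0.0883).

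Markers of monocyte-derived macrophages did not pass as a list (24 measured, 15 lower, median -0.05, camera adjusted p = 0.0932), although the list passed as lower without fl/fl S1 (median -0.16, adjusted p = 0.00457) or Mye-/- S8 (median -0.17, adjusted p = 0.00824), with array weights (0.0452), DESeq2 (0.0206) or limma-voom (0.0411), and without fl/fl S1 and S3 (0.0334). Its most abundant member, a feature that spans the neighbouring lysozyme genes Lyz2 and Lyz1 (chromosome 10, 117277334 to 117292868), was at 308919 ± 83367 in fl/fl and 169027 ± 24893 in Mye-/- (log2 fold change -0.84 ± 0.21 SE). Its adjusted p was 0.218 with limma and 8.1e-05 with DESeq2, and all 5 Mye-/- values were below all 4 fl/fl values. Hp, which encodes haptoglobin, was at 64757 ± 13000.2 and 45480.2 ± 4723, and S100a6 at 71796 ± 7349 and 56589 ± 3573.

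Genes of the pathways around MAGL, the enzyme labelled as deleted, did not pass as lists. The endocannabinoid enzyme list had 15 measured members, 6 higher and 9 lower (median -0.14, camera adjusted p = 0.562), and 0 passed either adjustment. Plcb2 and Plcg2, phospholipases C upstream of 2-arachidonoylglycerol, were at 1770.2 ± 468 and 12596 ± 706 in fl/fl and at 2382 ± 346 and 11431 ± 944 in Mye-/-. Naaa, an acylethanolamine hydrolase, was at 6941 ± 925 and 5942 ± 399, and Napepld at 54.3 ± 43.2 and 63.9 ± 37.2. Eicosanoid genes, whose products derive from arachidonic acid, had 11 higher and 12 lower of 23 (median -0.01, camera adjusted p = 0.712). Adjusted over that list alone 1 rose and 1 fell. These were Ptger4, a prostaglandin E2 receptor (871 ± 271 and 1479 ± 272), and Ltb4r1, the leukotriene B4 receptor (4952 ± 1588 and 3215 ± 479.7), while Ptger2, another prostaglandin E2 receptor, was at 1070.0 ± 135 and 655 ± 209.

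Inflammatory mediators did not pass (37 measured, 23 higher, median 0.10, camera adjusted p = 0.943), and the test's direction was lower while the median was higher. Adjusted over the list alone 1 member rose and 3 fell. Il1b, the inflammasome cytokine, was at 19381 ± 5378 in fl/fl and 32235 ± 6994 in Mye-/-, and the 3 lower members were Lcn2, S100a8 and S100a9. The list passed as lower without fl/fl S4 (median -0.12, adjusted p = 0.0325) and with detected features as a covariate (median -0.14, adjusted p = 0.00842), and without fl/fl S1 and S3 it passed as higher (median 0.20, adjusted p = 0.0310).

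Reparative markers had 16 of 25 higher (median 0.32, camera adjusted p = 0.0593). Adjusted over that list alone Klf4 and Gas6 rose, and Clec10a, a lectin of alternatively activated macrophages, fell, from 1536 ± 221 to 925 ± 289. The list passed as higher without fl/fl S4 (adjusted p = 0.0246) or Mye-/- S9 (adjusted p = 0.0139), with a pseudocount of 8 (0.0469) or 50 (0.0429), with quantile normalization (0.0175) and with detected features as a covariate (0.0122). Its median was 0.04 among the 17 members with a mean of at least 500, 0.19 without fl/fl S3, 0.11 without fl/fl S1 and S3, 0.13 without a filter, 0.15 with array weights, 0.20 with edgeR and 0.19 with DESeq2. Regenerative growth factors had 15 of 21 higher (median 0.28, camera adjusted p = 0.117), and Il1b alone rose when adjusted over the list. The median was 0.15 among the 10 members with a mean of at least 500, 0.18 without fl/fl S1, 0.47 without fl/fl S5, 0.42 without Mye-/- S11, 0.18 with edgeR and 0.17 with DESeq2. Vegfa was at 8587 ± 4885 and 11991 ± 2827, Hbegf at 94.6 ± 75.6 and 141 ± 50.3, and Inhba at 11.9 ± 23.7 and 54.4 ± 32.6. Autophagy genes had 19 higher and 21 lower of 40 (median -0.00379, camera adjusted p = 0.562), with Atg3 at 4816 ± 743 and 3518 ± 266, Gabarap at 21695 ± 1983 and 17498 ± 1628, Atg16l2 at 1085 ± 196 and 1525 ± 347, and Wipi2 at 1258 ± 365 and 1692 ± 275. The remaining 13 lists, for interferon gamma and antigen presentation, T and NK cells, cholesterol synthesis, cholesterol efflux, lipid storage, fatty acid synthesis, dendritic cells, NRF2 and iron, endothelium, matrix remodelling, lysosome, cholangiocytes and stellate cells, had camera adjusted p = 0.125 to 0.821. The median, the mean and the test's direction differed in sign for fatty acid synthesis, NRF2 and iron, endothelial, endocannabinoid, matrix, eicosanoid and cholangiocyte lists. Mitochondrial-encoded genes and B and plasma cell markers had fewer than 5 measured members and were not tested.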

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

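The tests of mouse age, of the Lyz2/Lyz1 feature, of other splits of the samples, of intronic features with a mean of at least 100 and of ribosomal protein genes were chosen only after the result was seen.

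In 19 of 196 groups of values, each group being the libraries of 1 genotype for 1 named gene or list score, 1 library lay far from the others. For normally distributed values chance would give such a library in about 1 of 20 groups. Read values are not normal and the groups share libraries, so an excess over chance was not measured. Of the 19, 8 were in Mye-/- S10. That library had a hepatocyte marker score of 2.74 (others -0.07 to 0.33), with Ttr at 1005 normalized reads (others 5.12 to 64.3) and Fgg at 759.6 (others 42.6 to 116). It also had Clec4f at 603 (others 33.3 to 143), Hpgd at 1480.2 (others 497 to 752), Gas6 at 358 (others 25.4 to 59.8), Cdk1 at 191 (others 27.3 to 40.6) and the feature of Hbb-bs and Hbb-b1 at 3035 (others 831 to 1414). In Mye-/- S9 the neutrophil gene S100a9 was at 6948 (others 1375 to 2189.8) and the mitotic gene Ube2c at 93.2 (others 0 to 20.5). Among fl/fl libraries, S1 had Ltb4r1 at 7327 (others 4046 to 4347) and Gas6 at 23.2 (others 0). Leng8 was at 1877 in fl/fl S3 (others 3279 to 3446). In fl/fl S4 Rbp4 was at 69.8 (others 0 to 11.6), Ttr at 166 (others 0) and the inflammatory mediator score at -0.82 (others 0.17 to 0.29). In fl/fl S5 Clec4f was at 73.8 (others 0), Inhba at 47.4 (others 0) and the unfolded protein response score at 0.24 (others 0.04 to 0.07).

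Type I interferon genes were higher in Mye-/- macrophages, with a median log2 fold change of 0.62. A general shift of genes at that expression level is argued against, since 10000 random lists matched on mean expression had medians of -0.11 to 0.10 (central 95%) and the list lay at percentile 100 of them. For this list taken alone 4 of 100 splits of the 9 libraries, the real one included, gave as many members as the 22 that passed adjusted over the list alone. The highest other gave 30. Chance is not excluded once the choice among 33 lists is counted (adjusted p = 0.276 for camera with an estimated correlation). The adjusted exact permutation p of 0.164 for the list score cannot decide this, because its smallest possible unadjusted p is 0.00794 and 1 list alone could not pass. Mouse age could not be separated from genotype by these models. All fl/fl mice were 11 weeks old, so with age in the model the difference rests on the 2 Mye-/- mice of that age, S8 and S12. That difference was 0.763 (95% interval 0.04 to 1.49), with 18 members past adjustment over the list alone. Among the 11-week-old mice alone it was the same, with an interval of -0.14 to 1.67 and 0 members past that adjustment. The scores of S8 and S12 were 0.72 and 0.09, against 0.13 in fl/fl S5. More Kupffer cells in the Mye-/- sorts cannot be told apart from a change within cells, because the genotype difference in the list score was 0.358 with the Kupffer marker score in the model (95% interval -0.34 to 1.06) and 0.65 without it (0.13 to 1.17), so part of the rise may go with Kupffer cells.

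All 50 nuclear genes of the respiratory chain were lower in Mye-/- macrophages, with a median of -0.33. Transcript length and GC content, each matched apart from the other in 5 strata, did not account for the whole fall at that resolution. Random lists matched on length and expression had medians of -0.20 to -0.04, and those matched on GC content and expression -0.13 to 0.06. The list lay at percentile 0 of both. Genes of matched length were lower too (median -0.12), and the ribosomal protein genes, at percentile 7.05 of their length-matched lists, stayed within that range. A finer match, or 1 on both properties at once, was not made, so their joint effect is not excluded. Random lists hold unrelated genes, so these percentiles can overstate how far a list of genes that vary together stands apart. For this list taken alone 1 of 100 splits, the real one, gave as many members as the 12 that passed adjusted over the list alone. The highest other gave 5. Splits were counted in the main setting, and in other settings the real count ran from 0 with edgeR to 17 with DESeq2. Chance is not excluded once the choice among 33 lists is counted (adjusted p = 0.196 for camera with an estimated correlation). The adjusted exact permutation p of 0.131 for the list score cannot decide this, because its smallest possible unadjusted p is 0.00794 and 1 list alone could not pass. A larger share of unspliced or nuclear RNA in the Mye-/- libraries stays open and is consistent with 941 features inside introns having a median of 0.53, at percentile 99.0 of random lists of named genes matched on expression (0.25 to 0.51), and the 210 with a mean of at least 100 a median of 0.42 against -0.02 to 0.19, while the share of reads in these features did not pass an exact permutation test (p = 0.0635). Lower respiratory chain expression and a different RNA composition of the libraries were not separated by these tests.

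The feature that spans Lyz2 and Lyz1 was lower in Mye-/- macrophages. A fall as large as this was not seen in the other 23 markers of monocyte-derived cells, which had a median of -0.0428 with an SD of 0.24, and all lay between -0.49 and 0.61. Fewer such cells are not excluded as part of the cause. Their list passed as lower in some settings, and Hp and S100a6 were lower with DESeq2 (adjusted p = 0.0273 and 0.0495). Itgam is among these markers, and its product CD11b was used for the sort. The share of other cells, such as neutrophils, was not tested for this feature. A Cre allele inserted in the Lyz2 locus, a common means of deletion in myeloid cells, is a candidate explanation that cannot be told apart from regulation or from a change in cell types: the log2 fold change was -0.84 (95% interval -1.28 to -0.41), which includes a loss of 1 of 2 copies, but the sources used here name no Cre line and the feature counts Lyz1 as well.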

How the results depend on the processing

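The pseudocount of 50, the mean of at least 500, the detected-feature covariate, the fit without fl/fl S1 and S3, and the counts over other splits were chosen only after the result was seen. No paired analysis was possible because the groups share no replicate numbers. Few genes passed, and which did so moved with the setting: limma called 3, edgeR 2 and DESeq2 146, and over 27 alternatives the call was lost in 6 for Mat2a, 10 for Id1 and 9 for GSMG0067294, with log2 fold changes of 1.10 to 1.26, 0.87 to 1.08 and 1.18 to 1.31. By the count of splits alone chance is under the 5% level for the number of genes, since 1 of 100 splits, the real one, gave as many as 3, but the highest other gave 2 and several settings gave 0, so it is not firmly excluded. It cannot be excluded for the number of lists, since 5 of 100 splits gave as many as the 13 called, the highest other gave 19 and the median of the others was 6, so calls at the preset correlation are common under other splits too. Directions of the largest lists held, with medians of 0.30 to 0.73 for type I interferon, -0.39 to -0.23 for the respiratory chain and -0.26 to -0.11 for ribosomal proteins over 30 alternatives, but no list passed with an estimated correlation or with fry. No list score passed the two-sided exact permutation test adjusted over the 33 lists, where the lowest adjusted p was 0.131. With a smallest possible p of 0.00794, 1 list alone could not pass that adjustment, so this outcome does not weigh against a list. Unadjusted, the p of this test was 0.0159 to 0.0952 for the hepatocyte, phagocytosis, fatty acid oxidation, Kupffer, immediate-early and ribosomal protein lists. Reads of low genes are not separate molecules. In simulation limma recovered 26.9% of 1.5-fold changes among genes with a mean of at least 500, so small changes can be missed in this design. Depth and sample number were not varied. Of values for single genes under alternatives, 1976 kept their direction and side of the threshold, 75 came to pass it, 25 ceased to and 11 changed sign; for lists these were 475, 12, 70 and 41.

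The number of genes changed was 17 with a pseudocount of 8 (12 higher, 5 lower), 6 with TMM scaling, 8 with quantile normalization, 9 with robust limma, 21 without an intensity trend, 5 with array weights, 0 with age as a covariate, 0 among 11-week-old mice, 146 with DESeq2 (91 higher, 55 lower), 8 with limma-voom, 17 with a pseudocount of 50, 12 among genes with a mean of at least 500, 0 with detected features as a covariate and 9 without fl/fl S1 and S3. At an unadjusted p under 0.05 the settings with 0 had 720, 506 and 938 features. Leaving out 1 library gave 0 to 20 genes. The number of lists changed was 8 at a mean of at least 500, 0 with an estimated correlation and 0 with fry, and 9 to 17 with 1 library left out. Apart from fewer genes or samples in some settings, the cause was not tested.

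Changes of sign came mostly from medians near 0. The eicosanoid median was 0.071 with a pseudocount of 0.5, 0.071 without a filter, 0.0316 at a mean of at least 50, 0.00671 with TMM, 0.00275 with quantile normalization, 0.00596 both with age as a covariate and among 11-week-old mice, and -0.126 to 0.062 with 1 library left out. The autophagy median was 0.0106 with TMM, 0.0242 with quantile normalization, 0.0231 with array weights, 0.0192 with edgeR, 0.00773 with DESeq2, 0.0012 with voom, 0.0399 at a mean of at least 500, 0.0263 with detected features and -0.0523 to 0.0413 with 1 library left out. The endocannabinoid median was 0.034 with edgeR, 0.023 with DESeq2, 0.00751 with a pseudocount of 50, 0.0771 without fl/fl S1 and S3, and -0.153 to 0.0147 with 1 library left out. The inflammatory mediator median was -0.0144 with edgeR, -0.0237 with DESeq2, -0.135 with detected features, 0.202 without fl/fl S1 and S3, where the test's direction turned, and -0.118 to 0.152 with 1 library left out. The monocyte-derived median was 0.0879 with age and among 11-week-old mice and -0.166 to 0.0147 with 1 library left out, and the platelet and erythroid median was 0.649 without a filter. Mgll ranged from -1.45 to 0.80 with 1 library left out. Itgam was at -0.0155 with detected features, -0.146 without fl/fl S1 and S3 and -0.038 to 0.101 with 1 library left out. Napepld was at -0.0811 with detected features and -0.302 to 1.94 with 1 library left out, and Vegfa at -0.0654 with detected features. For these changes of sign too, the cause was not tested.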

Other observations

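The proteasome group and the genes called by DESeq2 were looked at only after the result was seen, while the test of the genes around Mgll was chosen before.

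Genes of the proteasome, the protease that degrades ubiquitinated proteins, were lower in Mye-/- macrophages. Of 34 measured Psma, Psmb1 to Psmb7, Psmc and Psmd genes, 32 were lower and 2 higher, with a median log2 fold change of -0.33 (camera p = 2.0e-14, and p = 0.00527 with an estimated correlation, neither adjusted, for a group not fixed in advance). Most encode subunits of the 20S core or 19S cap, whereas Psmd5, Psmd9 and Psmd10 encode assembly factors of the cap. At an unadjusted limma p under 0.05, 16 were lower and 0 higher, and 14 passed when adjusted over the group alone, with 0 over all genes. Psmd13, a subunit of the 19S lid, was at 7126 ± 1113 normalized reads in fl/fl (SD, n = 4) and 4808 ± 699 in Mye-/- (SD, n = 5). The 19S ATPases Psmc2 and Psmc3 were at 4563 ± 376 and 8329 ± 648 in fl/fl and at 3152 ± 441 and 6135 ± 427 in Mye-/-. Psmb7, which carries the trypsin-like site, was at 7283 ± 852 and 5199 ± 685. Vcp, the ATPase that delivers ubiquitinated proteins to the proteasome, was at 10792.5 ± 2927 and 6593 ± 487 (DESeq2 adjusted p = 0.00614, limma adjusted p = 0.186).

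Several further genes were called by DESeq2 on the whole reads and not by limma, and those named here were chosen after the calls were seen. Siglec1, a sialic acid receptor of resident macrophages that interferon also induces, was at 259 ± 77.6 in fl/fl and 795 ± 424 in Mye-/- (DESeq2 adjusted p = 0.0305, limma adjusted p = 0.218). Csf2ra, the GM-CSF receptor alpha chain, was at 20827.5 ± 2657 and 29807 ± 3485, and Bcl6, a transcriptional repressor, at 2948 ± 489 and 4924 ± 1135. The polyamine enzymes Odc1, which makes putrescine, and Sat1, which acetylates spermidine and spermine, were at 3999.5 ± 462 and 63747 ± 4657 in fl/fl and at 6409.5 ± 1187 and 87063 ± 8529.6 in Mye-/-. C4b, a complement component, was at 361 ± 184 and 949 ± 218. Among lower calls, Lgals1, which encodes galectin 1, was at 17384 ± 1553 and 11967 ± 1102, Txn1, which encodes thioredoxin, at 20102 ± 2710.4 and 13869 ± 1457, and Tspo, a protein of the outer mitochondrial membrane, at 29522 ± 2093 and 20678 ± 3029. Prtn3, a granule protease of immature neutrophils and monocytes, was at 2455 ± 1127 and 1117 ± 270. Of the 91 higher calls, 40 were of features at 0 in all 4 fl/fl libraries, and 52 had a Mye-/- mean of at least 100. All 55 lower calls had a fl/fl mean of at least 100, and 0 were of features at 0 in all 5 Mye-/- libraries. Features detected in fl/fl S1, S3 and S4 (15547, 14696 and 14240) were fewer than in any Mye-/- library (15614 to 16802), while fl/fl S5 (16385) lay within that range. Higher expression and better detection of low features were therefore not separated for the 40.

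A lower output of the proteasome genes as a group was a first hypothesis. Their median lay at percentile 0 of 10000 random lists matched on mean expression (central 95% -0.13 to 0.09), so the group stands apart from genes at its level. It was found and tested on the same data, and transcript length, GC content and unspliced RNA were not tested for it.

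A second hypothesis was that sequence carried along with the engineered Mgll locus alters its neighbours. The controls are labelled fl/fl, so they would carry that sequence too if the deletion was made from the same allele. In that case it could not differ by genotype, and the test bears only on an effect of the deletion itself. Within 10 Mb of Mgll, 17 of 131 tested features (12.98%) had an unadjusted limma p under 0.05, against 1591 of 15157 elsewhere (10.5%, two-sided Fisher's exact p = 0.389), and 0 passed limma after adjustment over all genes. The Fisher test could not tell the shares apart, so an effect of the deletion on a few neighbours stays open. Of the 17, Rpn1 was called by DESeq2, at 13757 ± 1810 in fl/fl and 9543 ± 974 in Mye-/- (DESeq2 adjusted p = 0.00975, limma adjusted p = 0.218). Mat2a, on the same chromosome, lies 16.3 Mb from Mgll and outside that window.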
